A study of Homo sapiens with 16 samples.

How the data were processed

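RNA of MCF7 cells was measured on 16 Affymetrix Human Transcriptome Arrays (HTA 2.0). Per the labels' protocols, RNA was isolated with RNeasy columns and 100 ng was labelled with biotin by the WT PLUS kit. The deposited values are log2 signals per probe set, made by the authors with RMA (background correction, quantile normalization and summary of the probes of each set) in Affymetrix Expression Console, per the submitters' processing notes. Software versions, annotation and genome build are not given in the sources used here. The deposited log2 values lay between 1.58 and 14.22. RMA sets all arrays to a common distribution, so a change in total RNA per cell cannot be seen, and low signals are compressed, so folds of dim genes are understated.

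The table held 70523 probe sets. A platform annotation table named 1 gene for 23781 of them and several for 1543, and did not list 45199, which are unnamed here and not necessarily without a gene. Probe sets with several genes were not named. Symbols were updated through the RefSeq gene table of the GRCh38 assembly, used only for names: 21497 by gene number, 1974 by symbol and 306 by synonym, with 4 kept as given. No coordinates are given, because the build behind the probe sets is not named. Of 22411 genes, 528 had several probe sets, and the brightest by its mean over all arrays was taken. The 33.3% of genes with the lowest mean over all arrays were left out (below 5.35 on the log2 scale), which left 14941. The values of ESR2, which lies below that filter, come from a fit of all genes.

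Groups were taken from the labels. The titles call the arrays biological replicates without saying how the cultures were separated. The fourth sphere control has no treatment label and was placed by its description. Each gene was fitted with limma (lmFit and eBayes with a trend on mean level, limma 3.58.1 in R 4.3.3) in 1 model of all 16 arrays and 5 groups, which has 11 residual and 16.7 total degrees of freedom. The 7 contrasts were culture among controls, culture among DPN-treated cells, DPN in spheres, DPN/PHTPP in spheres, DPN/PHTPP against DPN in spheres, DPN in adherent cells, and the difference of the DPN effects between the cultures. Adjusted p-values are Benjamini-Hochberg values over the genes tested in limma, and the threshold was 0.05. Group means are given with the SD over arrays, and log2 changes with the SE of the fit. The median SE was 0.0418 for DPN in spheres and for the culture difference among controls, and the number of arrays limits the precision.

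The rule for named genes, the 27 gene lists and the alternatives were fixed before the data were examined. Named were the 10 largest rises and the 10 largest falls past the threshold whose groups did not overlap (where under 5 passed, the 5 smallest p are given as values), up to 4 members of each list past its test, and ESR1, ESR2, PGR, TFF1 and GREB1. Small RNAs, antisense and pseudogene entries and uncharacterized loci were passed over. Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast, with at least 5 measured members. Of 58 list calls over all contrasts, 2 held with a correlation estimated from the data. These were the hypoxia list with DPN in spheres and the estrogen receptor alpha target list with DPN in adherent cells, and each was lost without at least 1 array. List scores are means over members per array and were compared by exact two-sided permutation tests. Comparisons that share the control spheres were set beside 100 simulations of unchanged groups with genes drawn independently, for the correlation and for the overlap.

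The procedure was tested on simulated data with 200 changed genes among 14941. Of changes of 0.2 on the log2 scale 62.7% were recovered for DPN in spheres, 55.2% for DPN in adherent cells and 68.7% for culture, and of changes of 0.4 the shares were 92.5%, 98.5% and 100%. There were 9, 14 and 8 false calls beside 170, 168 and 179 true ones. For DPN in spheres, 20 of 20 simulated lists shifted by 0.2 were called, and 1 of 504 unshifted lists. Genes were drawn independently in these simulations. In the data the estimated correlation was 0.52 within the glycolysis and 0.57 within the cholesterol synthesis list. The share of false list calls in the data is thus not given by these simulations.

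The alternatives were a further quantile normalization, centring on array medians, no filter and a filter at the median, eBayes without a trend and robust eBayes, array weights, fits of the compared groups alone, the mean of a gene's probe sets, the replicate number as a block, an estimated correlation for camera, split controls, and leaving out each array. Cyclic loess between arrays, leaving out the pair of arrays of lowest weight, and leaving out each array with an estimated correlation were added after seeing the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.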

Results

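The series profiled MCF7 cells, an estrogen receptor positive luminal breast cancer line, on Affymetrix Human Transcriptome Arrays, and its stated aim was to follow what treatments do to the proliferation of the line. The 16 arrays fell into 5 groups. Spheres, which the labels call the cancer stem cell state, were kept in selective medium for 3 generations, then dissociated and treated as single cells. They gave 4 control arrays, 3 arrays with DPN (diarylpropionitrile, an agonist that prefers estrogen receptor beta) and 3 labelled DPN/PHTPP, where PHTPP is an antagonist that prefers the same receptor. Adherent monolayer cells, called the differentiated state, grew with 5% serum and gave 3 control arrays and 3 arrays with DPN. Compounds were used at 10 nM for 48 h. The treatment protocol names PHTPP or DPN for spheres, so whether the DPN/PHTPP cells received both compounds rests on the sample labels. The labels name no vehicle for the controls. Array medians over all probe sets lay between 4.97 and 5.16 on the log2 scale. The 3 adherent DPN arrays had medians of 4.97, 5.03 and 5.01, each below the 3 adherent controls at 5.06. Arrays of 1 group correlated at 0.998 to 0.9988 across genes, against 0.9778 to 0.9851 between spheres and adherent cells. The number of arrays per group limits the precision of every value below.

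Among the controls, cell cycle genes were lower in spheres than in adherent cells, and hypoxia, glycolysis, p53 and immediate-early genes were higher, as lists at the preset correlation of camera; no list call of this comparison held with an estimated correlation. NDC80, a kinetochore subunit, fell by 3.23 on the log2 scale, from 8.77 ± 0.08 (SD, n = 3) in adherent cells to 5.54 ± 0.09 (SD, n = 4) in spheres, a 9.38-fold difference. BMP5, a secreted growth factor of the bone morphogenetic protein family, was higher in spheres (8.5 ± 0.07, n = 4, against 4.97 ± 0.23, n = 3). CEACAM5, the carcinoembryonic antigen, was 6.63-fold higher (11.99 ± 0.04 against 9.26 ± 0.06), and PDZK1, a scaffold protein induced by estrogen, was lower (4.97 ± 0.06 against 7.67 ± 0.09). The adherent level of BMP5 and the sphere level of PDZK1 lay below the filter level of 5.35, where signals are compressed, so no fold is given for them. In all, 8944 of 14941 genes passed an adjusted p of 0.05 in limma, 4273 higher and 4671 lower in spheres, with a median absolute change of 0.29. Of these, 210 were at least 2-fold higher and 312 at least 2-fold lower, of which 31 and 28 had a group mean below the filter level. The majority direction of the calls depended on scaling. After a further quantile normalization 4748 genes were higher and 4433 lower in spheres, and after centring on array medians 4849 and 4241.

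The other large rises in spheres were TFPI, an inhibitor of the tissue factor pathway (log2 change 2.84 ± 0.05, SE), the protocadherin PCDH10 (2.74 ± 0.09), the adhesion molecule AMIGO2 (2.73 ± 0.06), the pseudokinase TRIB2 (2.72 ± 0.05), IGFBP5, which binds insulin-like growth factors (2.62 ± 0.06), the germline gene TDRD1 (2.5 ± 0.04), the hypoxia-induced hormone STC1 (2.48 ± 0.06) and the kinase PLK2 (2.43 ± 0.04). The other large falls were the secretory GTPase RAB3B (-2.86 ± 0.05), cyclin A2, CCNA2 (-2.68 ± 0.06), FAM72D (-2.61 ± 0.08), the spindle protein DLGAP5 (-2.4 ± 0.05), CEP55, which acts in the last step of cell division (-2.4 ± 0.05), DEPDC1B (-2.39 ± 0.04), SHCBP1 (-2.36 ± 0.06) and FAM72C (-2.36 ± 0.06). The changes of TFPI, PCDH10 and TDRD1 were taken against adherent means of 5.29, 5.34 and 4.06, below the filter level, and are not exact sizes. FAM72C and FAM72D are near-identical copies that array probes may not tell apart.

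Cell division genes fell together. All 23 measured G2/M genes were lower in spheres, with a median log2 change of -1.83, led by CCNA2, DLGAP5, HMMR (-2.35 ± 0.07) and CCNB2 (-2.28 ± 0.06). Their camera test had an adjusted p of 3.34e-17 and an adjusted p of 0.18 with an estimated correlation. All 23 G1/S and DNA replication genes were lower too (median -0.88, adjusted p = 1.09e-13, and 0.19 with an estimated correlation), including the replication licensing factor CDC6 (-1.53 ± 0.06), GINS1 (-1.38 ± 0.05), thymidylate synthase TYMS (-1.38 ± 0.04) and CLSPN (-1.31 ± 0.07). Of 8 replication-dependent histones 6 were lower and 2 higher (median -0.52, adjusted p = 0.0394, and 0.4 with an estimated correlation), with H1-4 at -1.25 ± 0.06 and H1-2 at -0.88 ± 0.08. Of 16 p53 target genes 15 were higher and none lower (median 0.46, adjusted p = 1.09e-06, and 0.13 with an estimated correlation), among them DDB2 in DNA repair (1.2 ± 0.03), the death receptor TNFRSF10B (0.94 ± 0.03), TP53INP1 (0.85 ± 0.04) and ZMAT3 (0.82 ± 0.05).

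Of 20 hypoxia response genes 17 were higher and 1 lower in spheres (median 0.75, adjusted p = 1.38e-07, and 0.22 with an estimated correlation). STC1, the collagen hydroxylase P4HA1 (1.49 ± 0.04), the mitophagy receptor BNIP3 (1.23 ± 0.05) and NDRG1 (1.1 ± 0.06) led them. Glycolysis genes rose in 17 of 19 cases with no fall (median 0.42, adjusted p = 2.53e-07, and 0.27 with an estimated correlation), with ALDOC at 1.74 ± 0.08, ENO2 at 1.69 ± 0.1, hexokinase HK2 at 1.36 ± 0.07 and PFKP at 0.9 ± 0.04. Oxidative phosphorylation genes were lower in 14 and higher in 2 of 20 cases (median -0.29, adjusted p = 0.00326, and 0.41 with an estimated correlation). NDUFV2 of complex I was at -0.71 ± 0.04, ATP5F1A of the ATP synthase at -0.69 ± 0.03 and SDHD at -0.56 ± 0.05, while COX6C was at 0.75 ± 0.04. Fatty acid synthesis and desaturation genes were lower in 10 of 12 cases (median -0.42, adjusted p = 0.000303, and 0.19 with an estimated correlation), including ACSL1 (-1.06 ± 0.04), acetyl-CoA carboxylase ACACA (-0.81 ± 0.06), the desaturase SCD (-0.71 ± 0.04) and ELOVL6 (-0.69 ± 0.04). Cholesterol synthesis genes were lower in 15 and higher in 2 of 20 cases (median -0.24, adjusted p = 0.00496, and 0.55 with an estimated correlation), with ACAT2 at -0.76 ± 0.05, EBP at -0.71 ± 0.05, SQLE at -0.7 ± 0.05 and INSIG1 at -0.68 ± 0.06.

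Target genes of estrogen receptor alpha were mostly lower in spheres. Of 26 measured, 17 were lower and 4 higher (median -0.34, adjusted p = 0.00167, and 0.23 with an estimated correlation). PDZK1, the amino acid transporter SLC7A5 (-1.77 ± 0.04), the secreted STC2 (-0.92 ± 0.04) and RERG (-0.88 ± 0.05) were lower, while GREB1, an estrogen-induced cofactor of the receptor, was higher (0.52 ± 0.04, adjusted p = 2.5e-09). PGR, the progesterone receptor, was lower (-0.35 ± 0.06, adjusted p = 0.00012), and TFF1 differed by 0.03 ± 0.03 (adjusted p = 0.3). The receptor ESR1 itself was lower by a small amount, -0.19 ± 0.04 (adjusted p = 0.0011). ESR2, which encodes estrogen receptor beta, had a mean log2 signal of 4.7, at the 25th percentile of genes and below the filter of 5.35, so it was left out of the count, and it differed by 0.08 ± 0.04 (adjusted p = 0.11 in a fit of all genes). ESR1 stood at 9.3, at the 94.4th percentile. Of 12 hormone receptors and cofactors 7 were higher and 3 lower (median 0.26, adjusted p = 0.0284, and 0.27 with an estimated correlation), led by the membrane estrogen receptor GPER1 (1.32 ± 0.06), the glucocorticoid receptor NR3C1 (0.67 ± 0.03), NCOA2 (0.58 ± 0.04) and RXRB (0.56 ± 0.04).

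Immediate-early and dissociation genes were higher in 16 and lower in 1 of 17 cases (median 0.57, adjusted p = 1.38e-07, and 0.19 with an estimated correlation). FOS was at 1.81 ± 0.04, ZFP36 at 1.1 ± 0.05, IER3 at 1.05 ± 0.04 and the heat shock gene HSPA1A at 0.78 ± 0.03. The protocol dissociated spheres, not monolayers, into single cells before the treatment step, and the cultures also differed in medium and serum. Whether any of these bears on the list was not tested. Aryl hydrocarbon receptor targets were lower in 6 and higher in 1 of 7 cases (median -0.21, adjusted p = 0.0219, and 0.19 with an estimated correlation), with CYP1A1 at -1.4 ± 0.08 and CYP1B1 at -0.67 ± 0.04; SLC7A5 is on this list and on that of estrogen receptor targets. The other 14 lists did not pass. Their members split as follows, higher before lower: stem cell markers 6 and 4 of 13 (adjusted p = 0.375), mesenchymal transition 5 and 4 of 13 (0.975), luminal markers 7 and 4 of 16 (0.382), basal markers 5 and 0 of 9 (0.0677), Notch signalling 6 and 4 of 16 (0.697), Wnt targets 2 and 6 of 12 (0.161) and the unfolded protein and amino acid stress response 7 and 6 of 18 (0.693). Interferon response genes split 6 and 2 of 11 (0.247), NF-kB and cytokine genes 4 and 2 of 8 (0.212), antioxidant genes 4 and 8 of 12 (0.34), fibroblast markers 3 and 0 of 6 (0.22), immune and endothelial markers 1 and 1 of 5 (0.693), cytosolic ribosomal proteins 2 and 6 of 13 (0.538) and housekeeping genes 3 and 5 of 10 (0.331). Adjusted over the list alone, each count of the 13 lists that passed moved by at most 1.

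The same culture difference was measured again in DPN-treated cells, on arrays not shared with the controls. Here 10597 genes passed, 5713 higher and 4884 lower in spheres, and the log2 changes correlated with those of the controls at r = 0.95 across genes, which are not independent replicates. Of the genes past the threshold in both, 3642 were higher in both and 4105 lower in both, against 1630 and 1530 for independent lists, while 44 went opposite ways. All 20 hypoxia genes were higher (median 0.94), with STC1 at 2.37 ± 0.06, ANGPTL4 at 1.65 ± 0.09, NDRG1 at 1.58 ± 0.06 and P4HA1 at 1.47 ± 0.04. All 23 G2/M genes were lower (median -2.13) and so were all 23 G1/S genes (median -0.99). Of the 26 estrogen receptor alpha targets 21 were lower and 4 higher (median -0.64), with MYBL1 at -1.49 ± 0.06 and PDZK1 at -3.24 ± 0.06, the latter against a sphere mean of 5.08, below the filter level. GREB1, higher in control spheres, differed by -0.01 ± 0.04 here (adjusted p = 0.84). These 4 lists passed camera (adjusted p = 8.62e-09, 7.77e-17, 3.63e-13 and 3.5e-06 in that order) and had adjusted p of 0.18, 0.14, 0.16 and 0.14 with an estimated correlation. Basal epithelial markers, not past the threshold in the controls, were higher in 7 of 9 cases (adjusted p = 0.0271, and 0.36 with an estimated correlation), while hormone receptors were not past it here (adjusted p = 0.102). Fibroblast markers (4 higher, 0 lower of 6, adjusted p = 0.067) and immune and endothelial markers (3 higher, 0 lower of 5, 0.218) did not pass. Dim genes as a whole lay higher in this contrast, with median changes of 0.091, 0.068, 0.001 and -0.055 over 4 equal bins of genes from the dimmest to the brightest. The glycolysis, oxidative phosphorylation, fatty acid, p53, immediate-early and histone lists passed here as in the controls, with adjusted p of 0.3, 0.36, 0.18, 0.14, 0.18 and 0.36 with an estimated correlation. The cholesterol list passed too, with an adjusted p of 0.033 (0.53 with an estimated correlation, 0.057 without sphere DPN replicate 3 and 0.0501 without adherent DPN replicate 1). The aryl hydrocarbon receptor targets had an adjusted p of 0.0499 (0.18 with an estimated correlation). It was 0.0506 to 0.0558 without sphere DPN replicate 1 or 3, any 1 DPN/PHTPP array, sphere control 2 or 3, adherent control 2 or any 1 adherent DPN array.

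**Figure D1:**
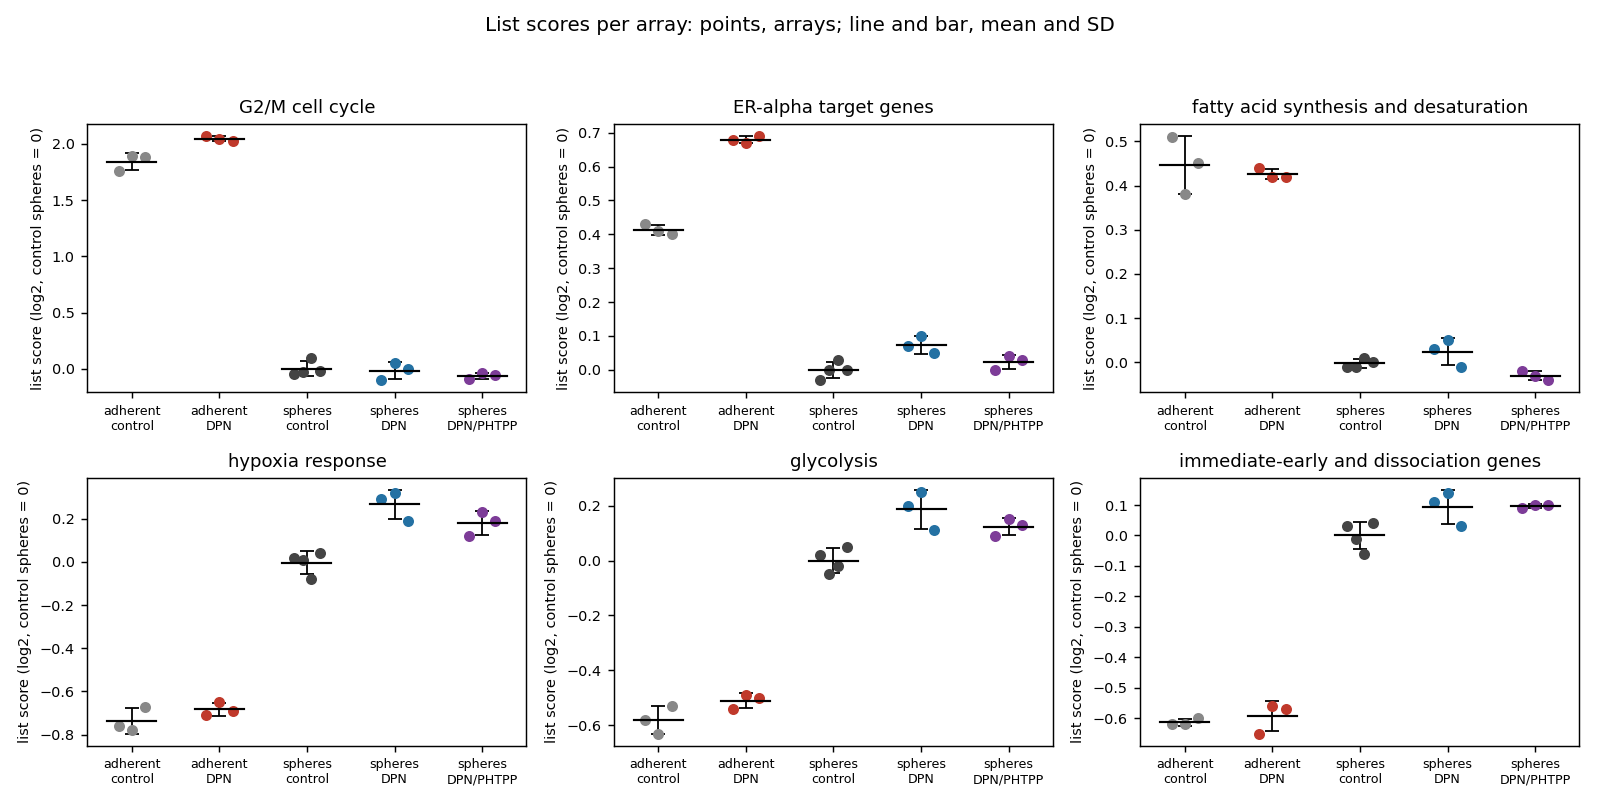
Each panel shows 1 gene list, with the mean log2 level of its members per array, set so that control spheres average 0, on the y axis and the 5 groups on the x axis; points are arrays, the horizontal line is the group mean and the bar its SD (n = 4 for control spheres, 3 for the others). The hypoxia score of the 3 DPN spheres lies at 0.19 to 0.32, above the 4 control spheres at -0.08 to 0.04, and the estrogen receptor alpha score of the adherent DPN arrays lies at 0.67 to 0.69, above the adherent controls at 0.4 to 0.43.

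In spheres, DPN was followed by higher hypoxia response genes, with changes under 2-fold. ANKRD37, a hypoxia-induced gene, rose 1.69-fold, from 7.53 ± 0.18 (SD, n = 4) to 8.29 ± 0.28 (SD, n = 3), with an adjusted p of 0.0043. HILPDA, a lipid droplet protein, rose 1.61-fold (8.81 ± 0.15 to 9.5 ± 0.2, adjusted p = 0.0023) and ADM, the vasodilator peptide adrenomedullin, 1.59-fold (7.28 ± 0.16 to 7.95 ± 0.21, adjusted p = 0.0051). In all 167 genes passed, 111 higher and 56 lower, with a median absolute change of 0.21, and none reached 2-fold. The other large rises were ENO2 (log2 change 0.57 ± 0.1, SE), POFUT4 (0.53 ± 0.07), the epithelial sodium channel subunit SCNN1G (0.52 ± 0.08), ANGPTL4 (0.45 ± 0.08), the glycolytic regulator PFKFB4 (0.42 ± 0.07), WSB1 (0.41 ± 0.07) and SFXN3 (0.4 ± 0.05). The falls were smaller. They were led by the metalloproteinase MMP16 (-0.39 ± 0.06), the sialyltransferase ST8SIA4 (-0.32 ± 0.05), the ectonucleotidase NT5E (-0.27 ± 0.05), ELOVL4 (-0.27 ± 0.05), TP53INP1 (-0.25 ± 0.04) and ODC1 of polyamine synthesis (-0.23 ± 0.04), with COA7, DOCK10, GRHL3 and TAF9B also at -0.23.

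Hypoxia response genes rose in 11 of 20 cases with no fall (median 0.21), and all 20 had a positive change. The camera test had an adjusted p of 4.21e-29 and an adjusted p of 0.032 with an estimated correlation, and adjusted over the list alone 19 members passed. The latter p was 0.052 to 0.075 without DPN replicate 1 or 2, sphere control 1 or 2, DPN/PHTPP replicate 3, or adherent DPN replicate 1 or 3, a check chosen after seeing the data. Glycolysis genes rose in 7 of 19 cases with no fall (median 0.15, adjusted p = 8.4e-22, and 0.092 with an estimated correlation; 16 adjusted over the list alone), among them PFKFB3 (0.32 ± 0.06) and HK2 (0.28 ± 0.07). The hypoxia score, the mean over the list per array, was 0.27 higher with DPN (exact two-sided permutation p = 0.029, the smallest that 3 against 4 arrays can give). The scores of 5 of the 27 lists reached that p, and adjusted over the 27 lists it was 0.15. Immediate-early genes passed as a list (adjusted p = 7.62e-08, and 0.2 with an estimated correlation) with IER3 (0.26 ± 0.04) and FOS (0.23 ± 0.04) as the members past the gene test. Estrogen receptor alpha targets rose in 4 of 26 cases with no fall (median 0.06, adjusted p = 9.26e-07, and 0.1 with an estimated correlation; 5 adjusted over the list alone). These were STC2 (0.35 ± 0.04), IGFBP4 (0.21 ± 0.03), GREB1 (0.19 ± 0.04) and CCN5 (0.18 ± 0.04), while PGR differed by 0.13 ± 0.06 (adjusted p = 0.42) and TFF1 by 0.05 ± 0.03 (0.41). ESR1 differed by -0.12 ± 0.04 (0.2). Histone, mesenchymal transition, Notch and ribosomal protein lists had adjusted p of 0.00446, 0.0195, 0.0195 and 0.0302 (0.2, 0.2, 0.2 and 0.43 with an estimated correlation), with ITGA5 (0.24 ± 0.05) their 1 member past the gene test. G2/M genes had no member past the test (median -0.02, adjusted p = 0.58).

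The sphere count moved with single arrays. It was 42 without DPN replicate 1, 97 without control 2, 44 without control 3 and 111 without control 4. Without DPN replicate 2 it was 80 and the direction of the majority turned, with 37 higher and 43 lower, while without DPN replicate 3 it was 185, with 160 higher and 25 lower. With array weights it was 745, 437 higher and 308 lower, and in a fit of the compared groups alone 86. The rule for named genes picked 30 genes as changed here, not all of them printed above. Of these, 14 kept an adjusted p under 0.05 in limma whichever array was left out, among them ANKRD37, HILPDA, ADM, PFKFB4, MMP16, STC2 and IGFBP4. Without DPN replicate 1 alone 12 of the 30 lost it, and without control 3 alone 11. The hypoxia, glycolysis, estrogen receptor alpha, immediate-early and histone lists kept their camera calls at the preset correlation without any 1 array. The Notch list lost its call without DPN replicate 1 (adjusted p = 0.091) and the mesenchymal list without DPN replicate 3 (0.054). The ribosomal list lost it without DPN replicate 1 (0.1), DPN replicate 2 (0.19), control 1 (0.086) or control 4 (0.059).

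Spheres labelled DPN/PHTPP differed from control spheres in 14 genes, 3 higher and 11 lower, with 2332 at an unadjusted p under 0.05. The count depended on the setting: it was 993 with array weights, 410 higher and 583 lower, and 0 in a limma fit of the compared groups alone. The weights leaned on DPN/PHTPP replicate 2 (3.27, against 1.03 and 0.68 for the other arrays of its group). FOS (log2 change 0.23 ± 0.04, SE), the transcription factor EGR4 (0.24 ± 0.04) and the sodium channel subunit SCNN1B (0.28 ± 0.04) were higher. MMP16 was 1.32-fold lower (-0.4 ± 0.06, adjusted p = 0.041). Also lower were the phosphatase PTPRG (-0.28 ± 0.05), SFT2D2 (-0.28 ± 0.05), the phosphate exporter XPR1 (-0.25 ± 0.04), SELENOI (-0.24 ± 0.04), TP53INP1 (-0.24 ± 0.04), MBNL3 (-0.23 ± 0.04), the mediator subunit MED1 (-0.23 ± 0.04), PHLPP2 (-0.22 ± 0.03, adjusted p = 0.019) and the receptor kinase ERBB4 (-0.21 ± 0.04). The rises with the smallest p that did not pass were IER3 (0.21, adjusted p = 0.061), SCNN1G (0.39, 0.072), STC2 (0.18, 0.072), SFXN3 (0.25, 0.072) and ENO2 (0.47, 0.072). ESR1 was at -0.22 ± 0.04 (0.072), PGR at 0.09 ± 0.06 (0.48), TFF1 at 0.03 ± 0.03 (0.6) and GREB1 at 0.11 ± 0.04 (0.22). As a list, hypoxia genes were higher (median 0.15, all 20 positive, adjusted p = 8.01e-13, and 0.36 with an estimated correlation) with no member past the gene test and 17 adjusted over the list alone. Glycolysis genes were likewise higher (median 0.08, adjusted p = 2.27e-08, and 0.36 with an estimated correlation; 10 adjusted over the list alone). The hypoxia score was 0.18 above the controls (exact permutation p = 0.029, the smallest possible). The scores of 11 of the 27 lists reached that p, and adjusted over the 27 lists it was 0.07.

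The immediate-early list also passed here (adjusted p = 1.91e-06), as did the basal (0.0089), mesenchymal (0.0164) and Notch (0.0164) lists as higher and the G2/M (0.00813) and G1/S (0.0164) lists as lower, with adjusted p of 0.36 to 0.59 with an estimated correlation. None of the 13 genes named here as changed kept an adjusted p under 0.05 whichever array was left out, and the count fell to 0 without DPN/PHTPP replicate 2, DPN/PHTPP replicate 3, control 2 or control 3 of the spheres. It was 1 to 5 without DPN replicate 1 or 2 or control 1 or 4 of the spheres, or without adherent DPN replicate 2 or adherent control 2 or 3, 7 without adherent control 1, 22 without DPN/PHTPP replicate 1 and 24 without sphere DPN replicate 3. The share of higher calls was 21.4%, and 50% of 24 calls after a further quantile normalization. Without DPN/PHTPP replicate 1 the G2/M, G1/S and Notch lists had adjusted p of 0.083, 0.11 and 0.072; without control 3 the first pair had 0.17 and 0.22, and without DPN/PHTPP replicate 3 the mesenchymal list had 0.062.

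DPN/PHTPP and DPN spheres, compared directly, differed in 0 genes past the threshold in limma, with 928 at an unadjusted p under 0.05, and in 28 genes, 14 higher and 14 lower, with array weights. The falls with the smallest p were PPP1R3C (-0.24 ± 0.04, adjusted p = 0.24), AKR1C2 (-0.2 ± 0.04, 0.39), NUP37 (-0.19 ± 0.04, 0.39), SCD (-0.18 ± 0.04, 0.73) and DIPK2A (-0.14 ± 0.03, 0.73). The rises with the smallest p were OXCT2 (0.2 ± 0.04, 0.3), CD8B2, TREML1, LNROP and PRRX2 (0.17 to 0.22, each with 0.73). ESR1 was at -0.1 ± 0.05, PGR at -0.03 ± 0.07, TFF1 at -0.02 ± 0.03 and GREB1 at -0.08 ± 0.04. As lists, hypoxia (median -0.07, adjusted p = 1.01e-06), glycolysis (-0.06, 6.2e-06), estrogen receptor alpha target (-0.04, 6.23e-06), fatty acid (-0.09, 0.000436), histone (-0.07, 0.00194) and G2/M genes (-0.05, 0.00466) were lower with PHTPP on the label and interferon genes (0.06, 0.00857) higher. All 7 lost the call with an estimated correlation (adjusted p of 0.38 to 0.76). The G2/M list lost it without sphere DPN replicate 2 (0.24), DPN replicate 3 (0.15) or DPN/PHTPP replicate 1 (0.095), and the interferon list without DPN replicate 3 (0.061) or DPN/PHTPP replicate 1 (0.52). The hypoxia score differed by -0.09 (exact permutation p = 0.3).

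The changes with DPN and with DPN/PHTPP share the control spheres. They correlated at r = 0.655 across genes, where simulated unchanged groups against the same controls gave a mean of 0.429, and their covariance was 0.00329 against a simulated 0.00116. The simulations, here and for the overlap below, drew genes independently. Relabelled DPN changes of spheres and adherent cells, which share no array, reached an absolute r of 0.426. The excess over the simulated values can thus not be judged. With the controls split into pairs the correlation of DPN and DPN/PHTPP changes was 0.244 to 0.518 over 6 assignments. Of the genes past the threshold in both, FOS and SCNN1B were higher, and MED1, MMP16, PHLPP2 and TP53INP1 lower, against 0.0223 and 0.0412 genes for independent lists. Independence is not the no-change value here, as the controls are shared. In 100 simulations of unchanged groups against shared controls, 0.01 genes on average (at most 1) passed the threshold in both. The strongest genes of those simulations, taken in lists of the observed sizes, shared 0.96 higher genes on average (at most 3) and 2.06 lower ones (at most 5). The number shared thus lay above the first value and within the range of the second, and how much of it came from the shared controls stayed open.

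In adherent cells, DPN was followed by higher estrogen receptor alpha target genes. PGR rose 1.75-fold, from 6.02 ± 0.06 (SD, n = 3) to 6.83 ± 0.15 (SD, n = 3), with an adjusted p of 1.5e-06. GREB1 rose 1.65-fold (8.76 ± 0.07 to 9.49 ± 0.03, adjusted p = 6.4e-08) and PDZK1 1.57-fold (7.67 ± 0.09 to 8.31 ± 0.11, adjusted p = 1.8e-06). Among the falls, VGLL1, a transcription cofactor, went from 7.21 ± 0.09 to 6.28 ± 0.16 and the keratin KRT4 from 7.94 ± 0.1 to 7.16 ± 0.05. In all 3702 of 14941 genes passed, 2039 higher and 1663 lower, with a median absolute change of 0.16, and none reached 2-fold.

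The other large rises were SYTL5 of vesicle traffic (log2 change 0.75 ± 0.05, SE), MYBL1 (0.69 ± 0.06), LONRF2 (0.67 ± 0.05), the GTPase RAB31 (0.64 ± 0.04), the protocadherin PCDHB8 (0.61 ± 0.09), the steroid glucuronidating enzyme UGT2B15 (0.58 ± 0.06) and the kinase JAK2 (0.56 ± 0.06). The other large falls were BPIFB1 (-0.67 ± 0.04), the interleukin receptor IL1R1 (-0.57 ± 0.05), ERP27 (-0.54 ± 0.09), the sodium channel subunit SCNN1A (-0.54 ± 0.04), the lactate receptor HCAR1 (-0.53 ± 0.05), the epithelial transcription factor GRHL3 (-0.49 ± 0.03), EMP1 (-0.49 ± 0.06) and the uroplakin UPK1A (-0.46 ± 0.05).

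Of the 26 estrogen receptor alpha targets 20 rose and 1, CCN5, fell (median 0.2, adjusted p = 2.38e-14, and 0.019 with an estimated correlation, or 0.054 without DPN replicate 3; 22 and 1 adjusted over the list alone). The score of the list was 0.27 higher with DPN (exact two-sided permutation p = 0.1, the smallest that 3 against 3 arrays can give). TFF1 was at 0.17 ± 0.03 (limma adjusted p = 0.0014), and ESR1 itself was lower, at -0.14 ± 0.05 (0.041). G2/M genes rose in 15 of 23 cases with no fall (median 0.19, adjusted p = 1.09e-07, and 0.66 with an estimated correlation; 21 adjusted over the list alone), with the kinetochore motor CENPE at 0.4 ± 0.09, ASPM at 0.34 ± 0.07, CDK1 at 0.31 ± 0.07 and KIF11 at 0.27 ± 0.07. Glycolysis genes rose in 4 of 19 cases (median 0.05, adjusted p = 0.0241), namely PGK1 (0.19 ± 0.04), LDHA (0.17 ± 0.04), PFKP (0.16 ± 0.04) and ENO1 (0.09 ± 0.03). Wnt targets fell in 5 of 12 cases (median -0.1, adjusted p = 0.0241), with BAMBI at -0.29 ± 0.04, NKD1 at -0.18 ± 0.06, DKK1 at -0.16 ± 0.04 and TNFRSF19 at -0.14 ± 0.04. Cholesterol synthesis genes fell in 4 and rose in 1 of 20 cases (median -0.08, adjusted p = 0.039), with MVD at -0.23 ± 0.08, HMGCS1 at -0.22 ± 0.08 and MVK at -0.2 ± 0.05, and STARD4 at 0.21 ± 0.07. With an estimated correlation these last lists had adjusted p of 0.8, 0.6 and 0.8. Hypoxia genes did not pass as a list (7 higher, 1 lower of 20, median 0.05, adjusted p = 0.108).

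The adherent count was 1043 without DPN replicate 1, 2101 without control 1, 1834 without control 2 and 2215 without control 3. After a further quantile normalization it was 2315, 1223 higher and 1092 lower. It was lower still in a fit of the compared groups alone, given with the processing settings below. The rule for named genes picked 38 genes as changed here, CCN5 not among them. Of these, 25 kept an adjusted p under 0.05 in limma whichever array was left out. The other 13 were ESR1, CDK1, KIF11, LDHA, PFKP, ENO1, NKD1, DKK1, TNFRSF19, MVD, HMGCS1, MVK and STARD4. The estrogen receptor alpha and G2/M lists kept their calls at the preset correlation without any 1 array. The glycolysis list lost its call without DPN replicate 2 (0.06), DPN replicate 3 (0.066) or control 2 (0.11), the Wnt list without DPN replicate 3 (0.052), and the cholesterol list without DPN replicate 2 (0.11), DPN replicate 3 (0.073), control 1 (0.19) or control 3 (0.23). Change depended on signal level, with medians of -0.074, -0.041, 0.016 and 0.047 over 4 equal bins of genes from the dimmest to the brightest, and 55.1% of the calls were higher, against 71.5% of 2833 calls after cyclic loess between arrays, a setting chosen after seeing the data.

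**Figure D2:**
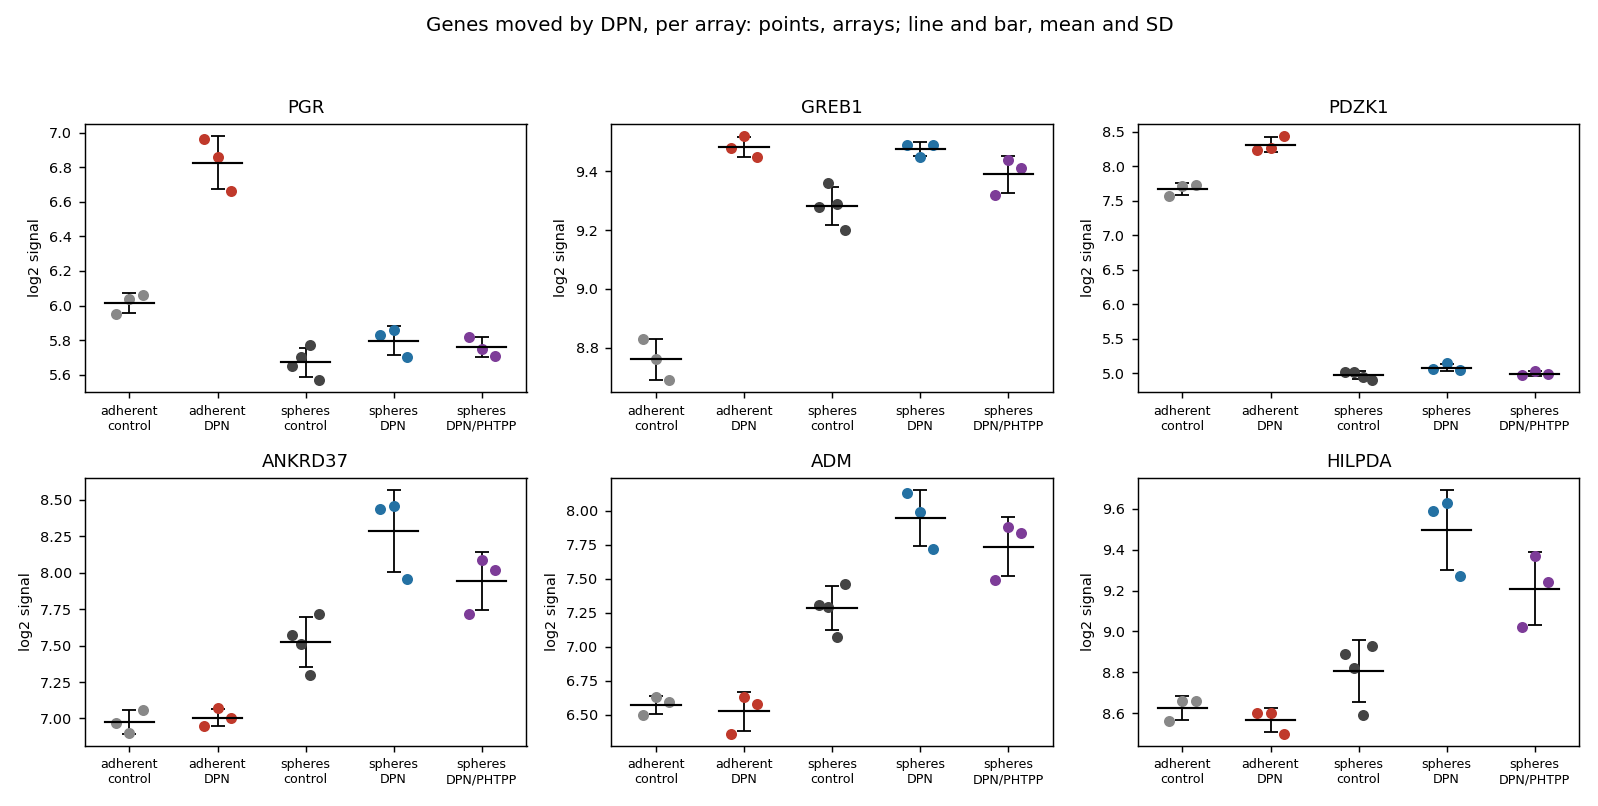
Log2 signal (y axis, a separate range in each panel) of 6 genes in the 5 groups (x axis); points are arrays, the horizontal line is the group mean and the bar its SD (n = 4 for control spheres, 3 for the others). PGR, GREB1 and PDZK1 are higher with DPN in adherent cells, PGR by 0.81, while ANKRD37, ADM and HILPDA are higher with DPN in spheres, ANKRD37 by 0.76.

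Whether the DPN response differed between the cultures was tested as an interaction, the change in spheres minus the change in adherent cells. It passed for 1760 genes, 551 positive and 1209 negative, and none reached 2-fold. The difference depended on signal level, with medians of 0.077, 0.042, -0.02 and -0.058 over 4 equal bins of genes from the dimmest to the brightest. In the dimmest bin 154 calls were positive and 111 negative, and in the brightest 86 and 463. Estrogen receptor alpha targets had the lower values in spheres. PGR differed by -0.68 ± 0.09 (SE, adjusted p = 0.00085), MYBL1 by -0.63 ± 0.09 and GREB1 by -0.53 ± 0.06 (adjusted p = 9.8e-05), and 11 of 26 list members were negative and 1 positive (median -0.15, adjusted p = 2.87e-06, and 0.29 with an estimated correlation; 15 and 1 adjusted over the list alone). PDZK1, 1 of the 11, had a value of -0.54 ± 0.08, but its sphere means of 4.97 and 5.08 lay below the filter level, so a smaller response in spheres is not shown for it. Hypoxia genes had the higher values in spheres, positive in 9 of 20 cases (median 0.15, adjusted p = 0.000241, and 0.6 with an estimated correlation; 10 adjusted over the list alone), with ANKRD37 at 0.73 ± 0.17, ADM at 0.72 ± 0.16, ANGPTL4 at 0.62 ± 0.12 and NDRG1 at 0.48 ± 0.09. G2/M genes were negative in 6 of 23 cases (median -0.2, adjusted p = 2.87e-06, and 0.6 with an estimated correlation; 13 adjusted over the list alone), with CENPE at -0.46 ± 0.12, ASPM at -0.45 ± 0.1, CENPF at -0.33 ± 0.08 and KIF11 at -0.3 ± 0.09. Glycolysis genes were positive in 4 of 19 cases (median 0.04, adjusted p = 0.029, and 0.6 with an estimated correlation), namely PFKFB4 (0.4 ± 0.1), HK2 (0.34 ± 0.1), PFKFB3 (0.28 ± 0.08) and the glucose transporter SLC2A1 (0.18 ± 0.05).

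The other large positive differences were KRT4 (0.8 ± 0.07), HILPDA (0.75 ± 0.13), UPK1A (0.65 ± 0.07), SCNN1G (0.62 ± 0.11), EMP1 (0.6 ± 0.08) and BPIFB1 (0.59 ± 0.06). VGLL1 had a value of 0.88 ± 0.11, but its sphere means of 5.02 and 4.97 lay below the filter level, as in 23 of the 1760 genes, where both means of 1 culture did. The other large negative ones were PCDHB8 (-0.68 ± 0.12), LONRF2 (-0.67 ± 0.07), the adaptor SHC4 (-0.62 ± 0.06), NT5DC3 (-0.6 ± 0.06), SYTL5 (-0.57 ± 0.07), AGR3 (-0.55 ± 0.09) and TMT1B (-0.54 ± 0.12). ESR1 differed by 0.01 ± 0.06 (adjusted p = 0.9) and TFF1 by -0.11 ± 0.04 (0.059). Across genes the DPN changes of the 2 cultures, which share no array, correlated at r = -0.0382 (Spearman rho = -0.122), and 538 of 700 relabellings of the arrays within each culture gave an r as far from 0. Of the genes higher with DPN in spheres 36 were also higher in adherent cells, against 15.1 for independent lists, and 4, namely CCN5, ELF3, SPAG4 and TCP11L2, were lower there, against 12.4. Of those lower in spheres 7 were lower in adherent cells too (6.23 for independent lists) and 15 higher (7.64). Independence is not the no-change value here, as the calls depended on signal level. Over 4 equal bins from the dimmest to the brightest genes, rises numbered 7, 17, 44 and 43 in spheres. In adherent cells rises numbered 217, 384, 613 and 825 and falls 610, 616, 298 and 139.

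The interaction count was 806 without sphere DPN replicate 1, 1105 without sphere DPN replicate 3, 952 without sphere control 2, 801 without sphere control 3, 1149, 931 and 1028 without adherent controls 1, 2 and 3, and 653 without adherent DPN replicate 1. Positive differences made 31.3% of the calls, and 42.5% of 1156 calls after a further quantile normalization. The glycolysis list lost its call without sphere DPN replicate 2 (0.1), sphere control 2 (0.057) or adherent control 3 (0.099), and the other 3 lists kept theirs at the preset correlation. Of the 30 genes named here as different, 24 kept an adjusted p under 0.05 whichever array was left out. The others were CENPE, KIF11 and all 4 named glycolysis genes, PFKFB4, HK2, PFKFB3 and SLC2A1.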

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

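The tests chosen only after the result was seen were the cyclic loess test and the estrogen receptor test of the gene counts, both tests of the estrogen receptor target list, and the tests of array spread and of handling for the hypoxia and glycolysis lists; the others were set out before.

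The response to DPN differed between spheres and adherent cells in the test of the difference itself for 1760 genes. Values are the change in spheres minus that in adherent cells, on the log2 scale. On the positive side VGLL1 stood at 0.88, KRT4 at 0.8, UPK1A at 0.65, SCNN1G at 0.62, EMP1 at 0.6 and BPIFB1 at 0.59. HILPDA stood at 0.75, and among members of the hypoxia and glycolysis lists ANKRD37 stood at 0.73, ADM at 0.72, ANGPTL4 at 0.62, NDRG1 at 0.48, PFKFB4 at 0.4, HK2 at 0.34, PFKFB3 at 0.28 and SLC2A1 at 0.18. On the negative side were PGR at -0.68, PCDHB8 at -0.68, LONRF2 at -0.67, MYBL1 at -0.63, SHC4 at -0.62, NT5DC3 at -0.6, SYTL5 at -0.57, AGR3 at -0.55, TMT1B at -0.54, PDZK1 at -0.54 and GREB1 at -0.53. The mitotic genes CENPE, ASPM, CENPF and KIF11 stood at -0.46, -0.45, -0.33 and -0.3. PFKFB4, HK2, PFKFB3, SLC2A1, CENPE and KIF11 lost the call without at least 1 array. The sphere means of VGLL1 (5.02 and 4.97) and PDZK1 (4.97 and 5.08) lay below the filter level of 5.35, where signals are compressed, so their values do not show that the response differed. As lists, the median was -0.15 for estrogen receptor alpha targets, 0.15 for hypoxia, 0.04 for glycolysis and -0.2 for G2/M genes. None of these 4 calls held with an estimated correlation (adjusted p = 0.29, 0.6, 0.6 and 0.6 in that order), and the glycolysis call at the preset correlation was lost without sphere DPN replicate 2 (0.1), sphere control 2 (0.057) or adherent control 3 (0.099).

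More genes passed with DPN in adherent cells (3702) than in spheres (167). A larger spread between sphere arrays is argued against, since the median residual SD of spheres was 0.921 times that of adherent arrays, and so is a trend with signal level as the whole cause, since 2833 genes passed in adherent cells after cyclic loess. How far the size of the count rests on adherent DPN replicate 1 stays open, since 1043 passed without it. The value that a response of estrogen receptor targets needs was there (camera adjusted p = 0.019 with an estimated correlation, 0.054 without adherent DPN replicate 3). However, the list has 26 tested members beside a count of 3702, and those that passed are part of that count. The value thus does not explain the count. The cultures also differed in medium and serum, which was not tested.

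The estrogen receptor alpha target list was higher with DPN in adherent cells, with 20 of 26 members past the gene test. Of the members 17 passed as higher after cyclic loess and 16 without adherent DPN replicate 1, which argues against a level trend and against that array as the whole cause. That DPN acts on these genes in adherent cells is a hypothesis, found and tested on the same arrays, and a vehicle effect may be open too, as the labels name none for the controls.

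The hypoxia list was higher with DPN in spheres (camera adjusted p = 0.032 with an estimated correlation) and so was the glycolysis list at the preset correlation, a call lost with an estimated one (0.092). Signal level is argued against, since the hypoxia median of 0.21 exceeded that of each of 10000 random lists matched on level (highest 0.05; 0.15 against 0.06 for glycolysis). Spread between sphere arrays stays open for both lists. The camera adjusted p for hypoxia with an estimated correlation was 0.061 without DPN replicate 1, 0.075 without DPN replicate 2, and 0.057 and 0.053 without controls 1 and 2. It was also 0.052 without DPN/PHTPP replicate 3 and 0.061 and 0.052 without adherent DPN replicates 1 and 3, arrays that do not enter the difference. For glycolysis it fell under the threshold without DPN replicate 3 alone (0.036). These are lost calls, not lost differences: the hypoxia scores were 0.19 to 0.32 with DPN and -0.08 to 0.04 in control spheres, with no overlap. Handling shared by treated cultures could not be told apart from the compound, since the score of DPN/PHTPP spheres was higher than in controls too (exact permutation p = 0.029, the smallest it can be, reached by 11 of 27 lists, and 0.07 adjusted over them), and sphere density or oxygen was not measured.

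Other splits of the arrays were counted for each comparison, with shares not adjusted over the 7 comparisons. For culture among controls 1 of 35 splits, the real one, gave 8944 genes or more (highest other 6603, which points to the culture structure of the arrays). For DPN in spheres 1 of 35 gave 167 (highest other 0). For these 2 the share is the smallest possible and is not adjusted over the 7 comparisons, so by itself it does not exclude chance. For culture, the DPN-treated arrays, not shared with the controls, gave changes correlated with those of the controls at r = 0.95 across genes. Of the genes past the threshold in both, 3642 were higher in both and 4105 lower in both, while 23 and 21 went opposite ways. These values argue against chance for the culture difference, not for DPN in spheres. For DPN/PHTPP 1 of 35, the smallest share possible, gave 14 (highest other 1), but 0 passed in a limma fit of the compared groups alone and without DPN/PHTPP replicate 2 or 3 or sphere control 2 or 3 (2332 genes at an unadjusted p under 0.05 with all arrays), so chance is left open there. For the DPN difference between cultures 1 of 100 drawn splits gave 1760 (highest other 1425). These splits relabelled DPN and control within each culture, so they stand for no DPN effect in either culture, not for equal effects. Whether chance gave the difference between the cultures was therefore not decided. With 10 splits a share under 0.05 cannot be reached for culture among DPN-treated cells (10597 genes, 1 of 10, highest other 0) or for DPN in adherent cells (3702, 1 of 10, highest other 0). For DPN/PHTPP against DPN in spheres all 10 of 10 splits gave 0 in limma, where 928 genes had an unadjusted p under 0.05 and 28 passed with array weights.

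Among 185 genes and lists checked in the 4 control spheres, 7 had 1 array apart from the rest, where chance gives about 5%. Replicate 3 stood apart for KRT4 (6.44), SCNN1B (7.63), SCNN1G (6.72), WSB1 (9.85) and ZFP36 (10.31), and replicate 2 for EBP (8.44) and ENO1 (11.53), all as log2 signals.

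Of the 45199 probe sets that the platform table does not list, the 42204 with a transcript cluster identifier were tested. No filter on dim probe sets was used, so the counts are not comparable with those of the named genes. For culture 8441 passed among controls and 10854 among DPN-treated cells, and 15 passed for the DPN difference between cultures. Of the 42204 probe sets 156 passed for DPN in adherent cells, 95 higher and 61 lower, and none for the 3 sphere treatment contrasts in limma, where 2666, 2856 and 2387 had an unadjusted p under 0.05.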

How the results depend on the processing

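Cyclic loess, leaving out the pair of arrays of lowest weight, and leaving out arrays with an estimated correlation were chosen after seeing the data; the other settings were planned. No named gene past the threshold and no list past its test reversed. Over the settings that change 1 choice, named genes gave 6894 values on the same side of the threshold, 445 no longer past it, 38 newly past it and 14 moved, and lists gave 1553 on the same side and 127 no longer past it. The culture counts stayed within 1.5 times in every setting run. The cause was not tested unless said.

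A further quantile normalization gave 24 genes for DPN/PHTPP in spheres, 2315 for DPN in adherent cells and 1156 for the difference of DPN effects. Centring gave 3 for DPN/PHTPP. Without the filter, where more genes share the adjustment, DPN in spheres gave 107 and DPN/PHTPP 1. eBayes without a trend gave 3 for DPN/PHTPP. Array weights gave 745 for DPN in spheres, 993 for DPN/PHTPP and 28 for DPN/PHTPP against DPN. In these groups 1 array had most of the weight. DPN/PHTPP replicate 2 had 3.27, against 1.03 and 0.68, and sphere DPN replicate 1 had 2.31, against 0.81 and 0.46. Fits of the compared groups alone, which have fewer degrees of freedom, gave 86 for DPN in spheres, 0 for DPN/PHTPP in limma (2332 genes at an unadjusted p under 0.05 in the fit of all groups) and 1481 for DPN in adherent cells. With an estimated correlation 2 of 58 list calls held, and each of these was lost without at least 1 array. Cyclic loess gave 1 for DPN/PHTPP. Without the arrays of lowest weight (adherent DPN replicate 1 at 0.36 and sphere DPN replicate 3 at 0.46) DPN/PHTPP gave 54, DPN in adherent cells 1184 and the difference 445. With split controls the correlation of DPN and DPN/PHTPP effects, which then share no control array, was 0.394, 0.383, 0.244, 0.518, 0.485 and 0.396 over the 6 assignments.

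Leaving out 1 array at a time, with fewer samples, gave 8398 to 9127 genes for culture among controls, 9643 to 10591 among DPN-treated cells, 42 to 198 for DPN in spheres, 0 to 24 for DPN/PHTPP, 0 to 0 for DPN/PHTPP against DPN (928 at an unadjusted p under 0.05 in limma with all arrays), 1043 to 4053 for DPN in adherent cells and 653 to 2453 for the difference. List calls numbered 52 to 63, and the correlations were -0.123 to 0.046 between cultures and 0.555 to 0.712 between DPN and DPN/PHTPP.

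With the replicate number as a block DPN in spheres gave 91 genes, and no other count moved by over 1.5 times. Sphere control 4 shares its number with no array and drops out of that estimate, and leaving it out alone gave 111, so the fall is not the block's alone. The numbers did not pair the arrays: 3 of 30 same-numbered pairs correlated over 0.1 in their deviations (median -0.005, range -0.32 to 0.33), and 4 of 15 arrays correlated best with their own number.

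Signal over background limits dim genes. ESR2 lay at 4.7, at the 25th percentile of genes, where RMA compresses a change.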

Other observations

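The genes named here were chosen after their values were seen; the test of opposition between DPN and culture was set out before, except that the spread was set beside its limit only afterwards.

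The stem cell marker list did not pass in control spheres against control adherent cells, and its members went both ways. CD44, a hyaluronan receptor, was higher in spheres (log2 change 1.65, 9.65 ± 0.03, SD, n = 4, against 8 ± 0.06, n = 3), as were the chemokine receptor CXCR4 (1.02), SOX9 (0.99), ITGB1 (0.49), KLF4 (0.38) and the transporter ABCG2 (0.31). MYC was lower (-1.04), as were ALDH1A3 (-0.84), the integrin ITGA6 (-0.8) and SOX2 (-0.75). With DPN in spheres CD44 rose by 0.2 (limma adjusted p = 0.0086) and CXCR4 by 0.26 (0.015). In adherent cells ITGA6 rose by 0.48 with DPN (6.5e-06) and ALDH1A3 fell by 0.33 (0.0028).

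Mesenchymal transition genes also went both ways between the control cultures. SNAI1, a repressor of epithelial genes, was higher in spheres (0.91), while TGFBI (-1.44), fibronectin FN1 (-0.64) and vimentin VIM (-0.51, with a sphere mean of 5.3, below the filter level of 5.35) were lower. CCN5, ELF3, SPAG4 and TCP11L2, the 4 genes higher with DPN in spheres and lower in adherent cells, differed between the cultures in their DPN change by 0.34, 0.38, 0.35 and 0.37. They were picked for opposite calls, so the sign of these values was fixed by the choice and is no test.

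A hypothesis was that DPN moves adherent cells away from the sphere profile, which predicts a correlation across genes under -0.1 between the DPN change in adherent cells and the sphere minus adherent difference. With no array shared, the correlations were -0.0591, -0.0629 and -0.0982, with a median of -0.0629 and an SD of 0.0216 over the 3 assignments of the adherent controls, and Spearman's rho was -0.0866, -0.078 and -0.123. All 3 Pearson values lay above the limit, the outcome set out before as going against the hypothesis. A margin of that SD, asked for only after the values were seen, was not met by 1 of them. The assignments share the control sphere and adherent DPN arrays, so that SD does not measure the spread between cultures. With the added margin the test left the hypothesis undecided.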
